A study of Homo sapiens with 20 samples.

How the data were processed

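The study profiled A549 cells, a lung adenocarcinoma line, on 2-colour Agilent SurePrint G3 Human GE 8x60K v2 arrays. Per the labels' protocols, cells were transfected with siRNA and harvested after 72 h, and 100 ng of total RNA per sample was copied from an oligo-dT primer and labelled. The sample carried Cy5 on all 20 arrays and a mixture of 20 cell lines carried Cy3, so no dyes were swapped and a dye effect of a probe stays in every ratio but cancels in differences between arrays. Groups came from the labels: 8 sicontrol arrays and 3 each of siMYMLR#1, siMYMLR#2, siMYC and siPCBP2. The description of each knockdown array names 1 control array, which always lay on the same slide.

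Per the file headers, the deposited scanner tables hold 62976 spots per array with intensity values on a linear scale, made with Feature Extraction 10.7.1.1 (protocol GE2_107_Sep09) for the 4 arrays of slide 1 and 10.10.1.1 (GE2_1010_Sep10) for the other 16. Per the file headers, the same tables hold processed intensity values, already background-subtracted and dye-normalized, and a LogRatio of Cy5 over Cy3 on a log10 scale. The authors' deposited value table of the series is on a log2 scale: it equalled the log2 form of those ratios within 0.001 for 100% of the probes on every array, its direction is therefore Cy5 over Cy3, its columns were not centred (medians from -0.20 to 0.27), and 0 of its columns could not be assigned to a sample. Probe coordinates are those of the files, in hg19 (GRCh37).

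From the scanner tables, median signal and median local background were corrected with normexp (offset 50), and log2 ratios of Cy5 over Cy3 were normalized within each array by loess with control spots at weight 0, in R 4.3.3 with limma 3.58.1 and data.table (1.17.8). Median signals were used because 16 of the files hold mean signals and the others do not. Control spots were then left out, spots with an outlier flag (0.606% to 1.01% per array) were set to missing, and spots of 1 probe were averaged. Of 50599 probes, the 30640 that were well above background in Cy5 on at least 3 of the 20 arrays were kept, and the brightest probe stood for each of 22902 genes. The median Cy5 signal was 94 to 147 per array against a background of 48 to 55, and at most 1 spot per array was saturated. Weak genes lie close to that background, where normexp pulls ratios toward 0. Probe names were updated through RefSeq tables (assembly GRCh38.p14, used for names only): 29996 probes matched by accession, 3093 by symbol and 481 by synonym, and 17029 kept the name in the file. Where a gene was not well above background on any array of 1 group, the text gives an "at least" fold, taken from single channels after loess and Aquantile scaling and open to dye bias without dye swaps.

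The tests were fitted with limma (lmFit and eBayes) on all 20 arrays together, with a term for each siRNA and the matched set of arrays as a fixed block, which left 8 residual degrees of freedom and 4.99 prior ones. Genes were called at a Benjamini-Hochberg adjusted p below 0.05 (two-sided) with no minimum fold. The comparisons were each siRNA with its controls, both MYMLR siRNAs averaged, siMYMLR#1 with siMYMLR#2, the MYMLR siRNAs with siMYC, and siPCBP2 with siMYC. The pairing comes from the labels. Deviations of knockdown arrays and own controls from group means correlated at 0.68, 0.68 and 0.86 for siMYMLR#1 and 0.08, 0.06 and -0.01 for siMYMLR#2. They did at 0.36, 0.24 and 0.16 for siMYC and 0.28, 0.10 and 0.13 for siPCBP2. Other controls reached 0.64, 0.03, 0.13 and 0.13, so this check is weak. Changes of matched pairs of 1 siRNA correlated at 0.864 to 0.946, and no array duplicated another (closest r = 0.990). The median gene SD was 0.167 over 8 controls (4 slides), 0.163 for siMYMLR#1 (2 slides) and 0.071 for siMYMLR#2 (1 slide). It was 0.099 for siMYC and 0.101 for siPCBP2.

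Gene lists (37, of pathways, MYC targets, complexes and markers of other cell types) were tested with camera, preset inter-gene correlation 0.01, and again with an estimated correlation, each adjusted over the 37 lists. Counts adjusted over the list alone repeat the Benjamini-Hochberg step on the list's own genes. The groups, comparisons, gene lists, rule for named genes and alternatives, but for those without slide 1 or slide 3, were chosen before the data were examined. That rule took MYC, PCBP2 and PVT1 everywhere, the 6 largest rises and 6 largest falls of each siRNA among called genes that moved the same way in every pair, carry an official-looking symbol and were well above background throughout the higher group, the 5 largest called differences each way for comparisons between siRNAs, and up to 4 members with the smallest adjusted p of each list described. Some genes that the rule takes are not reported here. Genes quoted for all 4 siRNAs were chosen after their values were seen. Slide was checked as a block and within each slide that held more than 1 group.

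Alternatives changed 1 choice at a time: no block, a random block, slide as the block, only the arrays of a comparison, the Feature Extraction log ratios, processed signals with loess, median centring, Aquantile scaling, Cy5 alone, the value table, no filter or a stricter one (10 arrays), the mean over probes, an intensity trend with robust estimation, array weights, a 2-fold minimum, rank correlation, an estimated camera correlation, and each array left out in turn. For correlations between comparisons that share control arrays, unchanged groups were simulated 100 times. A simulated siMYC comparison (200 of 22883 genes changed) recovered 12% of log2 changes of 0.25, 86% of 0.5 and 100% of 1 or 2. False calls were 7. The real fit called 51.2%, so rates may differ. Figures and tables used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.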

Results

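The arrays measured RNA of A549 cells 72 h after transfection of a small interfering RNA (siRNA). MYMLR is a long noncoding RNA transcribed divergently from the gene of the transcription factor MYC, and PCBP2 is a poly(C)-binding RNA-binding protein. There were 20 arrays: 8 of cells given a control siRNA (sicontrol), and 3 each of cells given siMYMLR#1, siMYMLR#2 (a second siRNA against MYMLR), siMYC or siPCBP2. Each array set 1 sample (Cy5) against a reference mixture of 20 cell lines (Cy3), and each knockdown array named its control array. Between 51.7% and 59.5% of probes were well above background in the sample channel of each array, and the number of arrays limits the precision. The labels do not say that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Changes are log2 changes of knockdown over matched control, given as mean ± SE from limma over 3 matched pairs unless stated, with limma's adjusted p over 22902 genes, and each gene named for a single siRNA moved the same way in all 3 of its matched pairs where it passed. A range beside the median of a called list is that over the normalization used and 6 others, given where any moved it by over 1.5 times.

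MYC messenger RNA was lower after all 4 siRNAs, including the one against PCBP2. Its probe was well above background on all 20 arrays. The 8 sicontrol arrays had a mean MYC log2 ratio to the reference of -0.17 ± 0.25 (SD, n = 8), and lay between -0.41 and 0.25. With siMYMLR#1 the 3 arrays read -1.38, -1.39 and -2.21, with siMYMLR#2 -1.49, -1.46 and -1.51, with siMYC -1.54, -1.84 and -1.75, and with siPCBP2 -1.08, -1.19 and -1.16. Against the matched controls MYC fell by 1.67 ± 0.06 after siMYMLR#1 (limma adjusted p = 2.87e-10) and by 1.26 ± 0.07 after siMYMLR#2 (adjusted p = 1.76e-09). It fell by 1.33 ± 0.06 after siMYC (adjusted p = 1.48e-09) and by 0.76 ± 0.06 after siPCBP2 (adjusted p = 1.78e-07), in 3 of 3 pairs each. Within slides the MYC change was -1.59 on slide 1 and -1.81 on slide 3 for siMYMLR#1, and -1.25 on slide 2 and -1.41 on slide 3 for siMYC. For siPCBP2 it was -0.79 on slide 2 and -0.79 on slide 3. A second probe annotated MYC was not well above background on any array.

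PCBP2 messenger RNA fell by 2.93 ± 0.06 after siPCBP2 (limma adjusted p = 4.24e-12, 3 of 3 pairs), with arrays at -3.84, -3.83 and -3.79 against a control mean of -0.83 ± 0.44 (SD, n = 8). Its probe (A_33_P3298492, NM_005016) lies at hg19 chromosome 12, 53873211 to 53873270. PCBP2 rose by 0.74 ± 0.06 after siMYMLR#1 (adjusted p = 3.53e-07), while its change after siMYMLR#2 was 0.05 (adjusted p = 0.584), and passed with the mean over probes (0.20, adjusted p = 0.0116). After siMYC it was 0.30 (adjusted p = 0.00127), a call lost without the pairing (0.23, adjusted p = 0.393), with the pairing as a random block (0.29, adjusted p = 0.105), under median centring (0.24, adjusted p = 0.0539), with the Cy5 channel alone (0.07, adjusted p = 0.263) and with the mean over probes (0.14, adjusted p = 0.0512). PVT1, a long noncoding RNA gene beside MYC, rose after siMYMLR#1 (0.36), siMYMLR#2 (0.50), siMYC (0.63) and siPCBP2 (0.57), by a probe at hg19 chromosome 8, 129004109 to 129004168. Its 10 probes did not move together: 6 went the other way after siMYMLR#1 and 1 each after siMYMLR#2 and siPCBP2, and the siMYMLR#1 call was lost with the mean over probes (0.08, adjusted p = 0.226) and under median centring (0.17, adjusted p = 0.163). Of 2 probes of CASC11, a noncoding gene on the other side of MYC, 1 was well above background on 1 array and the other on 0, too few to be tested, and no probe was annotated MYMLR, so the level of the targeted RNA itself was not measured.

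**Figure D1:**
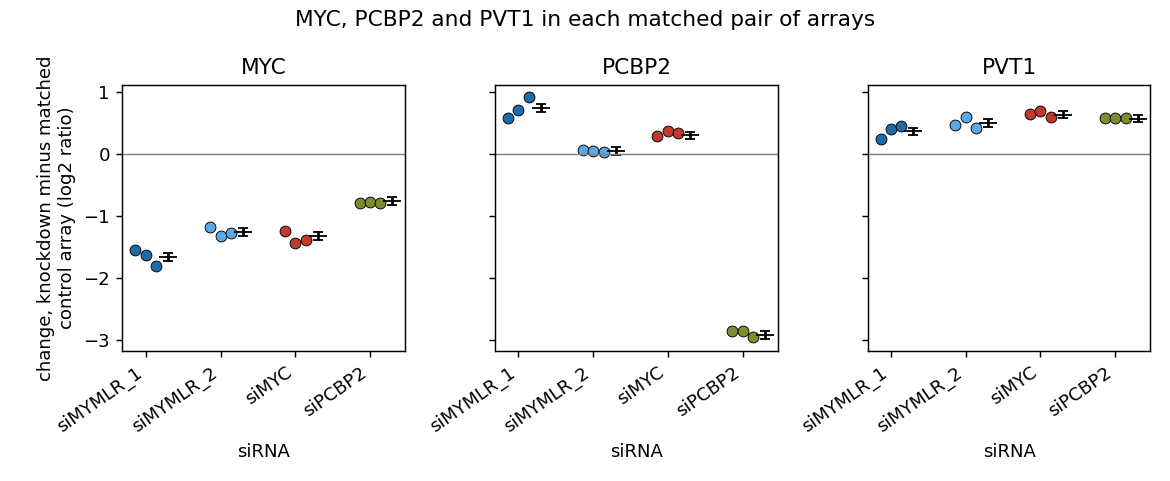
Change of MYC (left), PCBP2 (middle) and PVT1 (right), as the log2 ratio of a knockdown array minus that of its matched control array (vertical axis), by siRNA (horizontal axis, where siMYMLR_1 and siMYMLR_2 stand for siMYMLR#1 and siMYMLR#2); each coloured point is 1 matched pair and each black mark is the limma estimate with its SE. The estimates for MYC were -1.67, -1.26, -1.33 and -0.76 in the order drawn, all 12 MYC points lie below 0, and PCBP2 lies far below 0 after siPCBP2 alone (-2.93).

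After siMYMLR#1, which tests what loss of MYMLR does to gene expression, MYC-induced and ribosome biogenesis genes fell. The largest rises were of CITED4 (4.73 ± 0.10), a transcriptional co-activator, IL11 (3.74 ± 0.21), an interleukin-6 family cytokine, CCL2 (3.72 ± 0.18), a monocyte chemoattractant, COL5A1 (3.71 ± 0.17), a fibrillar collagen chain, NKAIN4 (3.59 ± 0.09) and NEURL3 (3.56 ± 0.12). The largest falls were of HMOX1 (-4.35 ± 0.30), which breaks down haem, ANXA1 (-3.27 ± 0.11), a phospholipid-binding annexin, GCSH (-3.07 ± 0.10) of the glycine cleavage system, PSAT1 (-2.88 ± 0.12) of serine synthesis, ASNS (-2.84 ± 0.11), which makes asparagine, and TMED10 (-2.84 ± 0.08), a cargo receptor of the early secretory pathway. Of these 12, the largest adjusted p was 6.14e-08. In all 6934 genes rose and 4782 fell at adjusted p below 0.05, of which 895 and 339 changed at least 2-fold. With each array centred on its median instead of loess the split was 4156 and 6994, and with the Cy5 channel alone 6144 and 6195.

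Of 57 MYC-induced genes, 46 fell, 2 rose and 9 did not pass (47 and 2 adjusted over the list alone) after siMYMLR#1. The median was -0.34 (range -0.68 to -0.34, camera adjusted p = 9.19e-13, and adjusted p = 0.0168 with an estimated correlation). They included NOP16 (-1.38) and GNL3 (-0.88), both nucleolar proteins, and MCM4 (-0.98) of the replicative helicase. In the list of 39 genes with MYC at their promoters, 24 fell, 2 rose and 13 did not pass (24 and 2 adjusted over the list alone). The median was -0.38 (range -0.73 to -0.38, camera adjusted p = 4.25e-08, and adjusted p = 0.00277 with an estimated correlation). APEX1 (-1.78), a base excision repair nuclease, and ODC1 (-1.44), the first enzyme of polyamine synthesis, were among them. Within slides the MYC-induced median was -0.36 on slide 1 and -0.31 on slide 3. Ribosome biogenesis genes moved the same way: of 75, 59 fell, 6 rose and 10 did not pass (61 and 6 adjusted over the list alone). Examples were MAK16 (-1.09) and NHP2 (-1.18). The median was -0.38 (range -0.64 to -0.38, camera adjusted p = 3.45e-12, and adjusted p = 0.00118 with an estimated correlation). Of 50 genes of the mitochondrial ribosome and protein import, 38 fell, 3 rose and 9 did not pass (39 and 3 adjusted over the list alone). They were led by C1QBP (-2.80), a mitochondrial matrix protein. The median was -0.34 (range -0.71 to -0.34, camera adjusted p = 1.31e-11, and adjusted p = 0.0227 with an estimated correlation). Of 19 aminoacyl-tRNA synthetase genes, 16 fell, 1 rose and 2 did not pass (16 and 1 adjusted over the list alone). Among them were YARS1 (-1.68) and MARS1 (-1.43). The median was -0.64 (range -1.0 to -0.64, camera adjusted p = 1.68e-08, and adjusted p = 0.168 with an estimated correlation). The 78 cytosolic ribosomal protein genes went less uniformly, and 23 fell, 8 rose and 47 did not pass (23 and 8 adjusted over the list alone). The median was -0.06 (range -0.59 to -0.05, camera adjusted p = 0.00355, and adjusted p = 0.587 with an estimated correlation). Their call was lost without the arrays of slide 1 (0.05, adjusted p = 0.699) and with the Cy5 channel alone (-0.05, adjusted p = 0.205). The amino acid and ER stress list split: of 41, 18 fell, 11 rose and 12 did not pass (18 and 11 adjusted over the list alone). The median was -0.11 (range -0.41 to -0.11, camera adjusted p = 0.0147, and adjusted p = 0.477 with an estimated correlation). That call was lost without the pairing (0.09, adjusted p = 0.738) and with it as a random block (-0.01, adjusted p = 0.173). Its strongest members fell: CHAC1 (-2.80), a glutathione-degrading enzyme, and PCK2 (-1.84), the mitochondrial phosphoenolpyruvate carboxykinase.

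Of 34 NF-kB targets and cytokines, 30 rose, 1 fell and 3 did not pass (31 and 1 adjusted over the list alone) after siMYMLR#1. The median was 0.97 (camera adjusted p = 1.16e-09, and adjusted p = 0.29 with an estimated correlation). IRAK2 (3.35), a kinase of interleukin-1 signalling, and C3 (2.89), the central complement component, rose, while PTGS2 (-1.85), the inducible prostaglandin synthase, fell. Of 55 interferon-stimulated genes, 33 rose, 3 fell and 19 did not pass (35 and 3 adjusted over the list alone). Among them were TAP1 (1.30) and PSMB9 (1.61) of antigen processing and GBP2, at least 2.74-fold higher. The median was 0.47 (range 0.35 to 0.77, camera adjusted p = 0.000528, and adjusted p = 0.536 with an estimated correlation). Of 43 p53 target genes, 27 rose, 4 fell and 12 did not pass (28 and 4 adjusted over the list alone). Among them were FUCA1 (1.73), TIGAR (1.80) and DRAM1 (1.37). The median was 0.39 (range 0.26 to 0.49, camera adjusted p = 0.000166, and adjusted p = 0.388 with an estimated correlation). TGF-beta target genes showed the same direction: of 25, 20 rose, 2 fell and 3 did not pass (20 and 2 adjusted over the list alone). The median was 0.69 (camera adjusted p = 5.09e-06, and adjusted p = 0.211 with an estimated correlation). Among them were PMEPA1 (2.90), a feedback inhibitor of that pathway, and JUNB (1.79). Of 24 mesenchymal markers, 17 rose, 2 fell and 5 did not pass (17 and 2 adjusted over the list alone). Among them were COL1A1 (2.62) and TAGLN (2.55). The median was 0.76 (range 0.49 to 1.01, camera adjusted p = 5.88e-05, and adjusted p = 0.231 with an estimated correlation). Beside them, of 9 markers of another cell type, fibroblasts, 5 rose, 0 fell and 4 did not pass (5 and 0 adjusted over the list alone). The median was 0.55 (camera adjusted p = 0.0147, and adjusted p = 0.168 with an estimated correlation), and 2 of them, COL1A1 and S100A4, are in both lists. That call was lost without the pairing (0.20, adjusted p = 0.0742). NRF2 targets, which answer oxidative stress, mostly fell: of 38, 23 fell, 9 rose and 6 did not pass (24 and 9 adjusted over the list alone). The median was -0.46 (range -0.75 to -0.39, camera adjusted p = 0.000528, and adjusted p = 0.435 with an estimated correlation). Examples were GSR (-1.38) and SRXN1 (-0.98). S-phase genes fell modestly: of 59, 41 fell, 7 rose and 11 did not pass (43 and 7 adjusted over the list alone), for example MCM6 (-0.95) and POLA1 (-0.73). The median was -0.32 (range -0.56 to -0.32, camera adjusted p = 2.69e-07, and adjusted p = 0.321 with an estimated correlation). Of 67 mitosis genes, 23 fell, 11 rose and 33 did not pass (23 and 10 adjusted over the list alone). The median was -0.06 (range -0.37 to -0.06, camera adjusted p = 0.0154, and adjusted p = 0.633 with an estimated correlation). Within slides it was 0.03 on slide 1 and -0.28 on slide 3, and the call was lost without siMYMLR#1 replicate 3 (0.03, adjusted p = 0.214), sicontrol replicate 4 (-0.01, adjusted p = 0.0802) or the arrays of slide 3 (0.03, adjusted p = 0.295). For siMYMLR#1, camera called 26 of the 37 lists with the preset correlation and 4 with an estimated one.

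After siMYMLR#2, every measured gene of the S-phase and mitosis lists fell. The largest falls were of HMOX1 (-4.85 ± 0.32) and of cell-cycle genes: HMMR (-3.44 ± 0.10), a spindle-associated hyaluronan receptor, CENPU (-3.37 ± 0.08) of the centromere, GINS2 (-3.33 ± 0.07) and CDC45 (-3.32 ± 0.09) of the replicative helicase, and SPC25 (-3.29 ± 0.14) of the kinetochore. The largest rises were of EDN2 (4.23 ± 0.14), a vasoconstrictor endothelin, GAS6-AS1 (3.50 ± 0.11), an antisense RNA, TP53INP1 (3.42 ± 0.14), a p53-induced nuclear protein, ANXA8L1 (3.35 ± 0.13), PAQR6 (3.22 ± 0.12) and SHC1 (3.08 ± 0.10), an adaptor of receptor tyrosine kinases. Of these 12, the largest adjusted p was 1.76e-08. At adjusted p below 0.05, 6888 genes rose and 5250 fell, of which 1130 and 938 changed at least 2-fold. Under median centring the split was 5126 and 6188. All 3 pairs lay on slide 4.

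All 59 S-phase genes fell after siMYMLR#2, also when adjusted over the list alone. The median was -2.01 (camera adjusted p = 1.88e-36, and adjusted p = 0.022 with an estimated correlation). DTL (-2.90), MCM7 (-2.67) and GINS3 (-2.69) fell by more than the median. All 67 mitosis genes fell too, likewise when adjusted over the list alone. Among them were CENPF (-3.08), CEP55 (-2.87) and CDCA5 (-2.83). The median was -2.10 (camera adjusted p = 9.66e-41, and adjusted p = 0.0732 with an estimated correlation). Of 21 replication-dependent histone genes, 19 fell, 2 rose and 0 did not pass (19 and 2 adjusted over the list alone). Among them were H4C3 (-2.67) and H2AC11 (-2.69). The median was -0.77 (camera adjusted p = 2.22e-08, and adjusted p = 0.255 with an estimated correlation). Nucleotide synthesis genes went with them: of 29, 19 fell, 4 rose and 6 did not pass (19 and 5 adjusted over the list alone). Among them was TK1 (-2.70), thymidine kinase. The median was -0.80 (camera adjusted p = 2.41e-07, and adjusted p = 0.022 with an estimated correlation). Of the 57 MYC-induced genes, 53 fell, 0 rose and 4 did not pass (54 and 0 adjusted over the list alone). The median was -0.70 (camera adjusted p = 1.02e-20, and adjusted p = 0.00356 with an estimated correlation). NOLC1 (-3.00), MCM4 (-2.85) and MRTO4 (-1.67) fell most clearly. Of the 39 MYC promoter-bound genes, 29 fell, 2 rose and 8 did not pass (29 and 2 adjusted over the list alone). Among them were NCL (-2.36), nucleolin, CDC25A (-2.44), a cell-cycle phosphatase, and TERT (-1.81), the telomerase reverse transcriptase. The median was -0.52 (camera adjusted p = 6e-10, and adjusted p = 0.00128 with an estimated correlation). Of 75 ribosome biogenesis genes, 58 fell, 7 rose and 10 did not pass (60 and 7 adjusted over the list alone), for example NOP58 (-1.50) and RRP15 (-1.55), though another RRP15 probe read 0.37. The median was -0.52 (camera adjusted p = 3.64e-14, and adjusted p = 0.000729 with an estimated correlation). The 78 cytosolic ribosomal protein genes went the other way, and 66 rose, 6 fell and 6 did not pass (69 and 6 adjusted over the list alone). The median was 0.41 (range 0.13 to 0.41, camera adjusted p = 5.57e-09, and adjusted p = 0.514 with an estimated correlation). RPS27 (0.98) and RPL13A (0.97) rose, while RPL14 (-2.66) and RPS13 (-1.52) fell, and 1 of 2 other RPS27 probes read -0.26.

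Chaperones and hnRNP genes fell after siMYMLR#2. Of 26 chaperone genes, 21 fell, 1 rose and 4 did not pass (21 and 1 adjusted over the list alone). Among them were HSP90AA1 (-1.98) and HSPA14 (-2.17). The median was -0.59 (camera adjusted p = 9.15e-09, and adjusted p = 0.0415 with an estimated correlation). Of 27 poly(C)-binding and hnRNP genes, which handle nascent RNA, 22 fell, 1 rose and 4 did not pass (22 and 1 adjusted over the list alone). The median was -0.73 (camera adjusted p = 2.2e-09, and adjusted p = 0.00356 with an estimated correlation). HNRNPU (-1.76) and HNRNPC (-1.37) fell and PCBP4 (1.42) rose. Of 50 mitochondrial ribosome and import genes, 38 fell, 2 rose and 10 did not pass (38 and 3 adjusted over the list alone). Those with the smallest adjusted p included MRPS28 (-1.79). The median was -0.44 (range -0.71 to -0.43, camera adjusted p = 6e-10, and adjusted p = 0.022 with an estimated correlation). Genes of the respiratory chain rose: of 50, 36 rose, 4 fell and 10 did not pass (37 and 4 adjusted over the list alone), for example COX7B (1.08). The median was 0.31 (range 0.08 to 0.31, camera adjusted p = 6.26e-06, and adjusted p = 0.358 with an estimated correlation); the call was lost under median centring (0.08, adjusted p = 0.0682). Of 43 p53 targets, 34 rose, 3 fell and 6 did not pass (34 and 4 adjusted over the list alone). Among them were CYFIP2 (2.60) and TIGAR (2.44). The median was 1.04 (camera adjusted p = 4.97e-09, and adjusted p = 0.255 with an estimated correlation). Interferon-stimulated genes rose broadly: of 55, 48 rose, 0 fell and 7 did not pass (48 and 0 adjusted over the list alone). The median was 0.85 (camera adjusted p = 3.28e-09, and adjusted p = 0.514 with an estimated correlation). STAT2 (1.17), which carries the type I interferon signal, and IFIT2 (1.39) rose, as did IFI44L, at least 5.26-fold higher. NF-kB targets were mixed and not called as a list: of 34, 11 rose, 6 fell and 17 did not pass (11 and 6 adjusted over the list alone). The median was 0.13 (camera adjusted p = 0.309, and adjusted p = 0.823 with an estimated correlation). Camera called 17 of the 37 lists for siMYMLR#2 with the preset correlation, and 8 with an estimated one.

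Averaged over both MYMLR siRNAs (6 matched pairs), which lessens but does not remove what belongs to 1 siRNA sequence, MYC fell by 1.46 ± 0.04 (limma adjusted p = 1.8e-11) and its induced genes fell almost without exception. The largest rises were of CITED4 (3.18 ± 0.08), ANXA8L1 (3.14 ± 0.09), CCL2 (3.08 ± 0.13), SCARNA22 (3.06 ± 0.08), a small Cajal body RNA, EDN2 (3.06 ± 0.10) and KRT80 (2.86 ± 0.07), a keratin. The largest falls were of HMOX1 (-4.60 ± 0.22), ANXA1 (-2.77 ± 0.08), ASNS (-2.70 ± 0.08), PCDH9 (-2.29 ± 0.10), a protocadherin, RPL22L1 (-2.21 ± 0.07), a ribosomal protein paralogue, and SNAR-G1 (-2.12 ± 0.08), a small noncoding RNA with near-identical copies whose probes cannot be assigned to 1 copy with certainty. Their largest adjusted p was 6.64e-10. The SE and p-values of such averages measure spread between arrays, not between siRNAs. In all 7824 genes rose and 5417 fell, of which 707 and 444 changed at least 2-fold, and under median centring the split was 5339 and 7598. Of 57 MYC-induced genes, 54 fell, 0 rose and 3 did not pass (54 and 0 adjusted over the list alone). The median was -0.55 (range -0.83 to -0.55, camera adjusted p = 7.65e-22, and adjusted p = 0.00317 with an estimated correlation). Of 39 MYC promoter-bound genes, 32 fell, 1 rose and 6 did not pass (32 and 1 adjusted over the list alone). The median was -0.51 (range -0.77 to -0.51, camera adjusted p = 2.12e-12, and adjusted p = 0.000549 with an estimated correlation). MCM4 (-1.91), NCL (-1.37) and GART (-1.16), a purine synthesis enzyme, were among them. Of 75 ribosome biogenesis genes, 64 fell, 5 rose and 6 did not pass (64 and 5 adjusted over the list alone), for example WDR12 (-1.11). The median was -0.41 (range -0.67 to -0.41, camera adjusted p = 3.04e-17, and adjusted p = 0.000342 with an estimated correlation). Among 43 p53 targets 34 rose, 3 fell and 6 did not pass (35 and 3 adjusted over the list alone). The median was 0.69 (camera adjusted p = 3.45e-08, and adjusted p = 0.262 with an estimated correlation). Among 55 interferon-stimulated genes 47 rose, 1 fell and 7 did not pass (47 and 1 adjusted over the list alone). The median was 0.68 (range 0.64 to 1.06, camera adjusted p = 3.45e-08, and adjusted p = 0.355 with an estimated correlation). CYFIP2 (2.13), TAP1 (1.40) and RIGI (1.28), a cytosolic RNA sensor, were examples. Of 78 ribosomal protein genes, 47 rose, 10 fell and 21 did not pass (48 and 11 adjusted over the list alone). The median was 0.15 (range -0.20 to 0.15, camera adjusted p = 0.0151, and adjusted p = 0.612 with an estimated correlation). The median turned to -0.20 under median centring. The call was lost without the pairing (0.13, adjusted p = 0.191), with Feature Extraction log ratios (adjusted p = 0.104), processed signals and loess (adjusted p = 0.958) or the Cy5 channel alone (0.04, adjusted p = 0.545), and without siMYMLR#1 replicate 3 (0.12, adjusted p = 0.0516). Of 59 S-phase genes 56 fell, 0 rose and 3 did not pass (56 and 0 adjusted over the list alone). The median was -1.11 (camera adjusted p = 3.53e-29, and adjusted p = 0.0393 with an estimated correlation). Of 67 mitosis genes 66 fell, 0 rose and 1 did not pass (66 and 0 adjusted over the list alone). The median was -1.17 (camera adjusted p = 6.17e-33, and adjusted p = 0.114 with an estimated correlation). Both averages rest mainly on siMYMLR#2 (medians above). Camera called 23 of the 37 lists with the preset correlation and 7 with an estimated one.

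After siMYC, the direct loss of MYC against which the MYMLR siRNAs are set, ribosome biogenesis and translation factor genes fell. Among the largest rises were IL11 (5.11 ± 0.21), EDN2 (4.64 ± 0.13), COL5A1 (3.75 ± 0.17), ACKR3 (3.75 ± 0.16), an atypical chemokine receptor, and IFI6 (3.60 ± 0.25), an interferon-induced protein. The largest falls were of RPL22L1 (-2.69 ± 0.09), HMOX1 (-2.48 ± 0.30), CTH (-2.44 ± 0.12), which makes cysteine, FGG (-2.40 ± 0.25), a fibrinogen chain, PTGS2 (-2.19 ± 0.08) and LEF1 (-2.19 ± 0.11), a Wnt pathway transcription factor. The largest adjusted p of these was 1.15e-05. In all 6610 genes rose and 5118 fell, of which 1145 and 347 changed at least 2-fold. The split was 7624 and 3669 under median centring, 5841 and 7096 with the Cy5 channel alone, and 5802 and 5874 with Feature Extraction log ratios.

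Of the 57 MYC-induced genes, 50 fell, 1 rose and 6 did not pass (51 and 1 adjusted over the list alone) after siMYC. Examples were GNL3 (-1.13) and HSPD1 (-1.08), a mitochondrial chaperonin. The median was -0.57 (camera adjusted p = 9.1e-18, and adjusted p = 0.00641 with an estimated correlation). Of the 39 MYC promoter-bound genes, 26 fell, 7 rose and 6 did not pass (26 and 7 adjusted over the list alone). Among them were ODC1 (-1.61) and TERT (-1.61). The median was -0.53 (camera adjusted p = 3.98e-07, and adjusted p = 0.00462 with an estimated correlation). Within slides the MYC-induced median was -0.62 on slide 2 and -0.52 on slide 3. Of 75 ribosome biogenesis genes, 65 fell, 4 rose and 6 did not pass (65 and 4 adjusted over the list alone). Among them were NLE1 (-1.36) and WDR12 (-1.17). The median was -0.52 (camera adjusted p = 9.1e-18, and adjusted p = 0.000287 with an estimated correlation). Ribosomal protein genes fell nearly as a block: of 78, 72 fell, 2 rose and 4 did not pass (73 and 2 adjusted over the list alone). The median was -0.80 (range -0.96 to -0.47, camera adjusted p = 8.65e-29, and adjusted p = 0.135 with an estimated correlation). Within slides it was -0.79 on slide 2 and -0.79 on slide 3. Examples were RPS24 (-1.62) and RPL12 (-1.22). Of 37 translation factor genes, 25 fell, 5 rose and 7 did not pass (26 and 5 adjusted over the list alone), for example EIF3E (-0.90) and EEF1G (-0.95). The median was -0.34 (camera adjusted p = 7.65e-07, and adjusted p = 0.0252 with an estimated correlation). Aminoacyl-tRNA synthetase genes fell as well: of 19, 17 fell, 0 rose and 2 did not pass (17 and 0 adjusted over the list alone). The median was -0.59 (camera adjusted p = 6.22e-08, and adjusted p = 0.135 with an estimated correlation). Genes that MYC is known to repress were not called as a list: of 30, 14 rose, 5 fell and 11 did not pass (14 and 5 adjusted over the list alone). Those that rose included S100A4 (3.00), TIMP2 (2.58), a metalloproteinase inhibitor, and LGALS1 (2.83), a galectin. The median was 0.19 (camera adjusted p = 0.0542, and adjusted p = 0.212 with an estimated correlation). Several alternatives did call it, for example the Cy5 channel alone (0.21, adjusted p = 0.023) and the pairing as a random block (0.13, adjusted p = 0.00464).

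The list of cholesterol synthesis and uptake genes rose after siMYC: of 34, 26 rose, 0 fell and 8 did not pass (27 and 0 adjusted over the list alone). The median was 0.45 (camera adjusted p = 3.98e-07, and adjusted p = 0.135 with an estimated correlation). Among them were FADS2 (1.82) and ACLY (1.91). Of 24 mesenchymal markers, 17 rose, 1 fell and 6 did not pass (17 and 1 adjusted over the list alone), for example CD44 (2.67), LOXL2 (2.66) and AXL (2.30). The median was 0.98 (camera adjusted p = 8.81e-07, and adjusted p = 0.135 with an estimated correlation). Another CD44 probe read -0.12. TGF-beta targets rose likewise: of 25, 20 rose, 2 fell and 3 did not pass (20 and 2 adjusted over the list alone). The median was 0.91 (camera adjusted p = 5.95e-07, and adjusted p = 0.135 with an estimated correlation). Of 9 fibroblast markers in the same samples, 4 rose, 2 fell and 3 did not pass (4 and 2 adjusted over the list alone). The median was 0.06 (camera adjusted p = 0.333, and adjusted p = 0.455 with an estimated correlation). Of 55 interferon-stimulated genes, 34 rose, 1 fell and 20 did not pass (38 and 1 adjusted over the list alone). Among them were ISG15 (2.95) and IRF7 (1.76). The median was 0.57 (range 0.57 to 1.19, camera adjusted p = 5.36e-06, and adjusted p = 0.455 with an estimated correlation). Within slides it was 0.93 on slide 2 and 0.51 on slide 3. KRT7 (2.40), an epithelial keratin, and SLC2A1 (1.92), a glucose transporter, also rose. S-phase genes fell modestly: of 59, 35 fell, 7 rose and 17 did not pass (37 and 7 adjusted over the list alone). The median was -0.25 (range -0.38 to -0.14, camera adjusted p = 1.4e-05, and adjusted p = 0.344 with an estimated correlation). EXO1 (-1.07) fell while CCNE2 (1.18) rose. Most mitosis genes did not pass: of 67, 16 fell, 9 rose and 42 did not pass (16 and 9 adjusted over the list alone). The median was -0.02 (camera adjusted p = 0.151, and adjusted p = 0.872 with an estimated correlation). Within slides it was 0.05 on slide 2 and -0.13 on slide 3, and it was 0.06 under median centring. Several alternatives called it lower, for example the Cy5 channel alone (-0.15, adjusted p = 0.0427). For siMYC, camera called 19 of the 37 lists with the preset correlation and 5 with an estimated one.

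After siPCBP2, which asks whether loss of this RNA-binding protein acts like loss of MYMLR, hnRNP and MYC-induced genes fell. The largest falls were of ASB4 (-4.06 ± 0.09), a SOCS-box protein, MTHFD2 (-3.61 ± 0.08), a mitochondrial folate enzyme, FABP5 (-3.32 ± 0.05), a fatty acid carrier, ABCD3 (-3.26 ± 0.07), a peroxisomal transporter, HNRNPA3 (-3.03 ± 0.09) and PCBP2 itself. The largest rises were of NEURL3 (4.11 ± 0.12), COL12A1 (3.94 ± 0.08), MT1F (3.67 ± 0.08), a metallothionein, EDN2 (3.40 ± 0.13), SCARNA13 (3.37 ± 0.15) and VIL1 (3.36 ± 0.18), an actin-bundling protein. Of these 12, the largest adjusted p was 3.82e-09. In all 7032 genes rose and 5318 fell, of which 1174 and 813 changed at least 2-fold.

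Of 67 mitosis genes, 66 fell, 0 rose and 1 did not pass (66 and 0 adjusted over the list alone) after siPCBP2, for example DEPDC1 (-2.31), KIF20A (-2.04) and HJURP (-1.94). The median was -1.04 (camera adjusted p = 5.14e-26, and adjusted p = 0.167 with an estimated correlation). Of 59 S-phase genes, 55 fell, 2 rose and 2 did not pass (55 and 2 adjusted over the list alone), for example POLA1 (-2.20) and CDC45 (-2.10). The median was -1.0 (camera adjusted p = 6.7e-23, and adjusted p = 0.0634 with an estimated correlation). The mitosis median was -0.82 on slide 2 and -1.15 on slide 3, and the S-phase median -0.88 and -1.11. MYC-induced genes fell: of 57, 41 fell, 1 rose and 15 did not pass (44 and 1 adjusted over the list alone). The median was -0.41 (camera adjusted p = 8.39e-13, and adjusted p = 0.014 with an estimated correlation), and it was -0.43 on slide 2 and -0.42 on slide 3. Among them were RCL1 (-1.80) and UNG (-1.40), a uracil glycosylase of DNA repair. Of the 39 MYC promoter-bound genes, 30 fell, 7 rose and 2 did not pass (30 and 7 adjusted over the list alone). The median was -0.62 (camera adjusted p = 1.14e-07, and adjusted p = 0.00361 with an estimated correlation). RRS1 (-1.59) fell while PPIF (1.17), mitochondrial cyclophilin, rose. Of 75 ribosome biogenesis genes, 50 fell, 6 rose and 19 did not pass (54 and 6 adjusted over the list alone), for example FTSJ3 (-1.63) and HEATR1 (-1.41), though another HEATR1 probe read 0.18. The median was -0.40 (camera adjusted p = 1.49e-10, and adjusted p = 0.00222 with an estimated correlation). Of the 78 ribosomal protein genes, 63 rose, 7 fell and 8 did not pass (63 and 7 adjusted over the list alone). The median was 0.33 (range 0.06 to 0.33, camera adjusted p = 8.62e-07, and adjusted p = 0.394 with an estimated correlation). RPL13A (0.89) and RPS19 (0.85) rose, RPL35A (-1.77) and RPL22 (-1.42) fell, the median was 0.40 on slide 2 and 0.33 on slide 3, and the call was lost with the Cy5 channel alone (0.06, adjusted p = 0.206). Of 26 chaperones, 21 fell, 1 rose and 4 did not pass (21 and 1 adjusted over the list alone). Among them were HSPH1 (-2.14) and CHORDC1 (-2.82). The median was -0.69 (camera adjusted p = 4.05e-09, and adjusted p = 0.0504 with an estimated correlation). The 27 poly(C)-binding and hnRNP genes, PCBP2 among them, mostly fell: 20 fell, 2 rose and 5 did not pass (22 and 2 adjusted over the list alone). The median was -0.80 (camera adjusted p = 1.39e-08, and adjusted p = 0.00634 with an estimated correlation). PCBP4 (1.54) was among those that rose.

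NRF2 targets fell after siPCBP2: of 38, 27 fell, 4 rose and 7 did not pass (27 and 4 adjusted over the list alone), for example TXNRD1 (-2.06), thioredoxin reductase, and ALDH3A1 (-2.14). The median was -0.64 (camera adjusted p = 3.07e-07, and adjusted p = 0.255 with an estimated correlation). Of 43 p53 targets, 33 rose, 4 fell and 6 did not pass (33 and 4 adjusted over the list alone), for example TNFRSF10B (1.83), a death receptor, and NINJ1 (1.64). The median was 0.78 (camera adjusted p = 1.55e-08, and adjusted p = 0.231 with an estimated correlation). NF-kB targets and cytokines rose too: of 34, 24 rose, 1 fell and 9 did not pass (25 and 1 adjusted over the list alone). The median was 0.63 (camera adjusted p = 3.24e-05, and adjusted p = 0.379 with an estimated correlation). Among them were CCL2 (2.93) and RELB (2.41). Interferon-stimulated genes were not called as a list: of 55, 19 rose, 4 fell and 32 did not pass (18 and 4 adjusted over the list alone). The median was 0.19 (camera adjusted p = 0.132, and adjusted p = 0.785 with an estimated correlation). TAP1 (2.60) was among those that rose. Some alternatives called it, for example with the arrays of the comparison alone (0.20, adjusted p = 0.00866). Of 31 epithelial markers, 17 rose, 0 fell and 14 did not pass (17 and 0 adjusted over the list alone). Those with the smallest adjusted p included CDH1 (2.53), E-cadherin. The median was 0.28 (range 0.18 to 0.38, camera adjusted p = 0.00096, and adjusted p = 0.231 with an estimated correlation). Mesenchymal markers rose in the same samples: of 24, 16 rose, 2 fell and 6 did not pass (16 and 3 adjusted over the list alone). The median was 0.74 (camera adjusted p = 0.000418, and adjusted p = 0.231 with an estimated correlation). Within slides it was 1.14 on slide 2 and 0.79 on slide 3. Glycolysis genes mostly fell: of 24, 14 fell, 4 rose and 6 did not pass (16 and 4 adjusted over the list alone), for example LDHB (-2.32) and LDHA (-0.90), the lactate dehydrogenase subunits. The median was -0.26 (camera adjusted p = 0.00211, and adjusted p = 0.119 with an estimated correlation). The list of cholesterol synthesis and uptake genes split: of 34, 10 rose, 11 fell and 13 did not pass (10 and 11 adjusted over the list alone). The median was 0.02 (camera adjusted p = 0.731, and adjusted p = 0.903 with an estimated correlation), and within slides it lay between -0.11 and 0.07. SQLE (-1.97) and SCD (-2.46) fell. For siPCBP2, camera called 22 of the 37 lists with the preset correlation and 4 with an estimated one.

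Of 33 lysosome and autophagy genes, 21 rose, 6 fell and 6 did not pass (21 and 6 adjusted over the list alone) after siMYMLR#1. The median was 0.39 (range 0.10 to 0.39, camera adjusted p = 0.000528, and adjusted p = 0.368 with an estimated correlation). After siMYMLR#2, 22 rose, 5 fell and 6 did not pass (22 and 5 adjusted over the list alone). The median was 0.31 (range 0.12 to 0.36, camera adjusted p = 0.00187, and adjusted p = 0.532 with an estimated correlation). After siMYC, 23 rose, 3 fell and 7 did not pass (23 and 3 adjusted over the list alone). The median was 0.51 (range 0.33 to 0.58, camera adjusted p = 8.28e-05, and adjusted p = 0.304 with an estimated correlation). After siPCBP2, 25 rose, 5 fell and 3 did not pass (25 and 5 adjusted over the list alone). The median was 0.51 (camera adjusted p = 4.39e-05, and adjusted p = 0.286 with an estimated correlation). Of 26 hypoxia genes, 15 rose, 3 fell and 8 did not pass (16 and 4 adjusted over the list alone) after siMYC. The median was 0.27 (camera adjusted p = 0.00509, and adjusted p = 0.189 with an estimated correlation). Camera called none of the lists of immediate early genes, lung lineage genes, the MYC/MAX/MXD network or genes around MYC on its chromosome arm after any of the 4 siRNAs, with smallest adjusted p of 0.0515, 0.119, 0.138 and 0.0925. Among markers of other cell types, of 14 squamous and basal cell genes, 8 rose, 0 fell and 6 did not pass (8 and 0 adjusted over the list alone) after siMYMLR#1. The median was 0.34 (range 0.15 to 0.58, camera adjusted p = 0.0164, and adjusted p = 0.168 with an estimated correlation). That call was lost with the Cy5 channel alone (0.21, adjusted p = 0.0713). Of 16 neuroendocrine genes, 7 fell, 0 rose and 9 did not pass (7 and 0 adjusted over the list alone) after siPCBP2. The median was -0.10 (range -0.28 to -0.09, camera adjusted p = 0.0226, and adjusted p = 0.301 with an estimated correlation), and the call was lost in several alternatives, for example without the pairing (-0.04, adjusted p = 0.0551). Blood cell markers had medians of 0.06, 0.03, 0.02 and 0.03 after siMYMLR#1, siMYMLR#2, siMYC and siPCBP2, with no camera adjusted p below 0.235. Fibroblast markers had medians of 0.10 after siMYMLR#2 and 0.08 after siPCBP2, with camera adjusted p of 0.304 and 0.155.

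**Figure D2:**
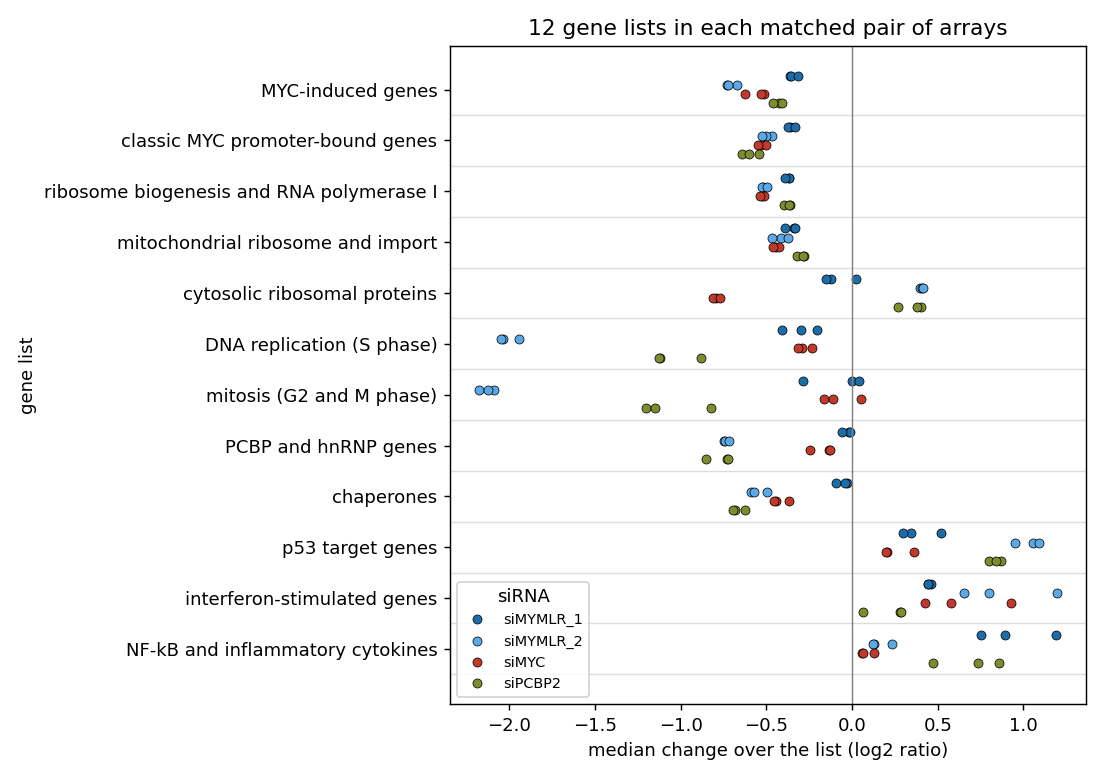
Median log2 change (horizontal axis) of 12 gene lists (vertical axis) in each of the 12 matched pairs of knockdown and control arrays, coloured by siRNA (siMYMLR_1 and siMYMLR_2 stand for siMYMLR#1 and siMYMLR#2); each point is 1 pair. Mitosis and S-phase medians lie lowest for siMYMLR#2 (-2.10 and -2.01). Ribosomal protein medians lie below 0 for siMYC (-0.80) and above 0 for siMYMLR#2 (0.41) and siPCBP2 (0.33).

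The MYMLR siRNAs differed from each other in 10141 genes (siMYMLR#1 minus siMYMLR#2, 3 pairs each: 5375 higher and 4766 lower, of which 1129 and 878 by at least 2-fold). The majority turned under median centring (4098 higher and 4683 lower), with Feature Extraction log ratios (4914 and 5238) and with the Cy5 channel alone (5320 and 5955). HMMR (3.85 ± 0.13), CENPU (3.43 ± 0.11), SDS (3.38 ± 0.13), a serine dehydratase, NKAIN4 (3.20 ± 0.13) and CITED4 (3.10 ± 0.15) were most above, and TMA7 (-3.60 ± 0.13), SHC1 (-3.08 ± 0.13), RPS20 (-2.97 ± 0.10), CASK (-2.93 ± 0.12), a membrane scaffold kinase, and TMEM50A (-2.90 ± 0.10) most below, with adjusted p of 4.12e-09 or less. The MYC difference was -0.41 ± 0.09 (limma adjusted p = 0.00206), a call lost without the pairing (-0.17, adjusted p = 0.484) and with it as a random block (-0.29, adjusted p = 0.0997), and the PCBP2 difference was 0.69 (adjusted p = 2.59e-05). Of 67 mitosis genes 65 were higher, 0 were lower and 2 did not pass (65 and 0 adjusted over the list alone) after siMYMLR#1. The median was 2.07 (camera adjusted p = 1.22e-37, and adjusted p = 0.141 with an estimated correlation). Of 59 S-phase genes 57 were higher, 0 were lower and 2 did not pass (57 and 0 adjusted over the list alone). The median was 1.69 (camera adjusted p = 2.03e-32, and adjusted p = 0.104 with an estimated correlation). NF-kB targets were higher after siMYMLR#1: of 34, 24 were higher, 1 was lower and 9 did not pass (26 and 1 adjusted over the list alone). The median was 1.12 (camera adjusted p = 1.85e-06, and adjusted p = 0.528 with an estimated correlation). Ribosomal protein genes were lower: of 78, 62 were lower, 3 were higher and 13 did not pass (64 and 3 adjusted over the list alone). The median was -0.48 (range -0.83 to -0.14, camera adjusted p = 1.61e-13, and adjusted p = 0.415 with an estimated correlation). Of the 27 poly(C)-binding and hnRNP genes, 22 were higher, 2 were lower and 3 did not pass (22 and 2 adjusted over the list alone). The median was 0.78 (camera adjusted p = 5.39e-08, and adjusted p = 0.0236 with an estimated correlation). Of the 15 lists called, this 1 held with an estimated correlation. MYC-induced genes had a smaller fall after siMYMLR#1: of 57, 29 were higher, 4 were lower and 24 did not pass (29 and 4 adjusted over the list alone). The median was 0.32 (range 0.21 to 0.32, camera adjusted p = 2.09e-05, and adjusted p = 0.141 with an estimated correlation).

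Set against siMYC, the MYMLR siRNAs together (6 pairs against 3) differed in 15 lists by camera with the preset correlation, of which 0 held with an estimated one, and MYC itself was not called different. The MYC difference was -0.13 ± 0.07 (limma adjusted p = 0.167), and -0.46 under median centring (adjusted p = 0.00381), which moved the median of all genes in this comparison from 0.01 to -0.17. SCARNA16 (2.46 ± 0.14), COLEC11 (2.33 ± 0.09), a collectin, SCARNA13 (2.23 ± 0.17), IL6 (2.21 ± 0.32) and TCIM (2.12 ± 0.15) were most above siMYC. CD44 (-3.07 ± 0.09), the hyaluronan receptor, SLC2A1 (-2.86 ± 0.09), PHLDA2 (-2.75 ± 0.10), F2RL1 (-2.74 ± 0.12), a protease-activated receptor, and IL11 (-2.40 ± 0.24) were most below, all with adjusted p of 8.88e-05 or less. The SCARNA16 call was lost without the pairing (1.30, adjusted p = 0.178). In all 4520 genes were higher and 4801 lower, of which 329 and 550 by at least 2-fold, and the split was 2060 and 8803 under median centring, 4630 and 4466 with Feature Extraction log ratios and 5879 and 4597 with the Cy5 channel alone. Of 78 ribosomal protein genes 73 were higher, 4 were lower and 1 did not pass (74 and 4 adjusted over the list alone) after the MYMLR siRNAs. The median was 0.90 (range 0.47 to 0.90, camera adjusted p = 1.51e-36, and adjusted p = 0.142 with an estimated correlation). Of 67 mitosis genes 65 were lower, 0 were higher and 2 did not pass (66 and 0 adjusted over the list alone). The median was -1.10 (camera adjusted p = 3.87e-34, and adjusted p = 0.142 with an estimated correlation). Of 59 S-phase genes 55 were lower, 2 were higher and 2 did not pass (56 and 2 adjusted over the list alone). The median was -0.88 (camera adjusted p = 1.49e-25, and adjusted p = 0.137 with an estimated correlation). Here too siMYMLR#2 stood apart: the mitosis median was -2.10 after it, -0.06 after siMYMLR#1 and -0.02 after siMYC, and the S-phase medians -2.01, -0.32 and -0.25. The p53 targets stood higher after the MYMLR siRNAs: of 43, 27 were higher, 4 were lower and 12 did not pass (27 and 4 adjusted over the list alone). The median was 0.54 (range 0.24 to 0.69, camera adjusted p = 6.93e-07, and adjusted p = 0.403 with an estimated correlation). Mesenchymal markers stood lower: of 24, 12 were lower, 3 were higher and 9 did not pass (12 and 3 adjusted over the list alone). The median was -0.43 (range -0.80 to -0.43, camera adjusted p = 0.00528, and adjusted p = 0.403 with an estimated correlation). MYC-induced genes were not called: of 57, 18 were higher, 14 lower and 25 did not pass (19 and 15 adjusted over the list alone). The median was 0.00 (camera adjusted p = 0.944, and adjusted p = 0.956 with an estimated correlation), and it was -0.33 under median centring, where the list was called (adjusted p = 0.0332).

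**Figure D3:**
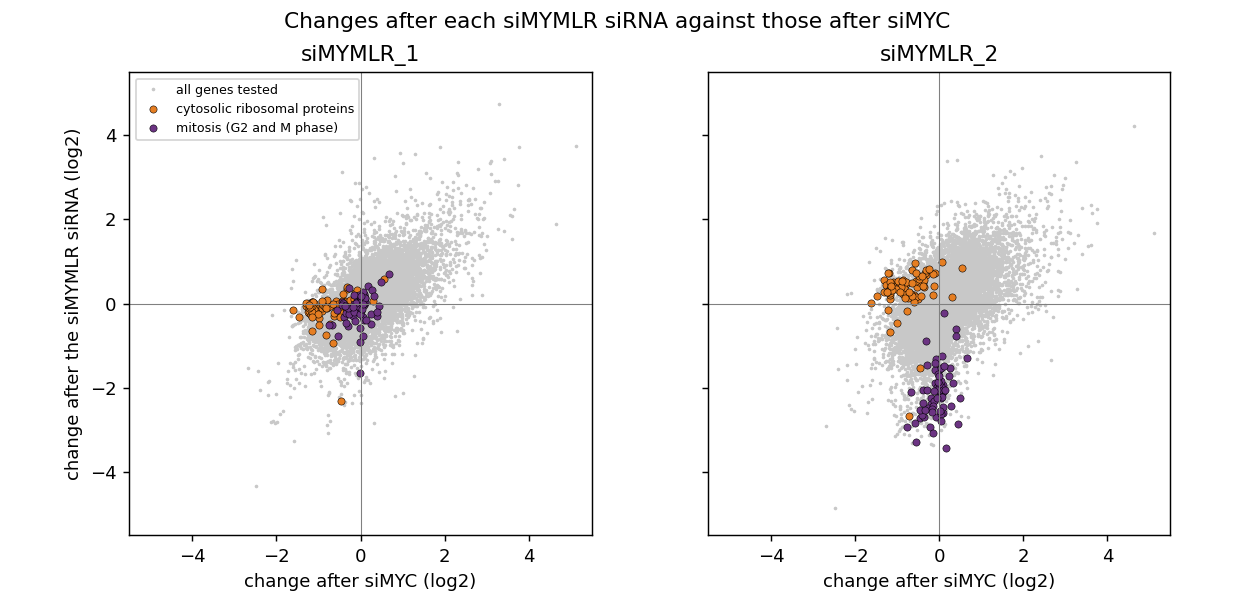
Log2 change after siMYC (horizontal axis of both panels) against the log2 change after siMYMLR#1 (left) and siMYMLR#2 (right, vertical axes); each grey point is 1 of 22902 genes, orange points are 78 cytosolic ribosomal protein genes and purple points are 67 mitosis genes. Pearson correlations across genes were 0.622 and 0.481.

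Set against siMYC on the same 3 control arrays, siPCBP2 left MYC higher by 0.57 (limma adjusted p = 5.18e-06) and differed in 11829 genes, 5806 higher and 6023 lower, of which 696 and 1012 by at least 2-fold. The split was 4589 and 6693 under median centring, 6244 and 5597 with Feature Extraction log ratios and 7018 and 5910 with the Cy5 channel alone. SCARNA13 (3.59 ± 0.15), RPL22L1 (3.06 ± 0.10), SCARNA16 (3.03 ± 0.13), MT1F (3.02 ± 0.09) and SNORA79 (2.97 ± 0.13) were most above siMYC, and IL11 (-4.59 ± 0.22), NT5E (-3.46 ± 0.11), an ectonucleotidase, ASB4 (-3.46 ± 0.09), SCD (-3.45 ± 0.09), a fatty acid desaturase, and MALL (-3.44 ± 0.12) most below, with adjusted p of 1.3e-09 or less. Ribosomal protein genes stood higher after siPCBP2: of 78, 73 were higher, 3 were lower and 2 did not pass (73 and 3 adjusted over the list alone). The median was 1.04 (range 0.48 to 1.14, camera adjusted p = 2.5e-30, and adjusted p = 0.242 with an estimated correlation), and it was 1.08 on slide 2 and 1.01 on slide 3. Mitosis genes stood lower: of 67, 66 were lower, 0 were higher and 1 did not pass (66 and 0 adjusted over the list alone). The median was -0.96 (camera adjusted p = 1.87e-23, and adjusted p = 0.242 with an estimated correlation). S-phase genes stood lower too: of 59, 52 were lower, 1 was higher and 6 did not pass (52 and 1 adjusted over the list alone). The median was -0.79 (camera adjusted p = 3.2e-16, and adjusted p = 0.242 with an estimated correlation). Glycolysis genes also stood lower: of 24, 18 were lower, 4 were higher and 2 did not pass (19 and 5 adjusted over the list alone). The median was -0.51 (camera adjusted p = 8.29e-05, and adjusted p = 0.101 with an estimated correlation). The p53 targets stood higher: of 43, 31 were higher, 3 were lower and 9 did not pass (32 and 3 adjusted over the list alone). The median was 0.57 (camera adjusted p = 5.86e-08, and adjusted p = 0.298 with an estimated correlation). MYC-induced genes were not called: of 57, 30 were higher, 18 were lower and 9 did not pass (31 and 18 adjusted over the list alone). The median was 0.18 (camera adjusted p = 0.347, and adjusted p = 0.72 with an estimated correlation). Camera called 16 lists with the preset correlation and 0 with an estimated one.

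The 4 siRNAs shared many changes: 2042 genes rose and 1271 fell after all 4, where independent lists would share 184.8 and 56.9. Unchanged groups simulated on these control arrays shared 0 limma calls in each of 100 simulations, for all 4 siRNAs and for each pair of them (at unadjusted p below 0.05, a mean of 1 rise and 0.8 falls for all 4, and of 113.6 and 113.2 for siPCBP2 and siMYC). The simulated value leaves out the effects and the independent one the shared controls, so neither difference measures a shared effect. At least 2-fold in all 4, 155 genes rose and 18 fell. Among them were HMOX1 (-4.35, -4.85, -2.48 and -2.11 in the order siMYMLR#1, siMYMLR#2, siMYC, siPCBP2), ASNS (-2.84, -2.56, -2.03 and -2.08), TIMP2 (2.47, 2.33, 2.58 and 2.63) and EDN2 (1.89, 4.23, 4.64 and 3.40). Across 22902 genes, which are not independent replicates, log2 changes after siMYMLR#1 and siMYC correlated with Pearson r = 0.622 (Spearman 0.566), where unchanged groups simulated on the 1 shared control array gave 0.210. The covariance was 0.156 against a simulated 0.00166, and without the shared control r was 0.599. siMYMLR#2 and siMYC share no control array, and gave r = 0.481 (simulated 0.002). The average of the MYMLR siRNAs correlated with siMYC at 0.642 (simulated 0.146, and 0.614 without the shared control). siPCBP2 and siMYC share all 3 control arrays, and gave 0.510 against a simulated 0.465, with a covariance of 0.148 against 0.00372, and 0.50 on slide 2 and 0.533 on slide 3. Part of that correlation may come from the shared controls. With siPCBP2, siMYMLR#1 correlated at 0.481 (simulated 0.212, and 0.458 without the shared control), siMYMLR#2 at 0.542 (simulated 0) and their average at 0.607 (simulated 0.147, and 0.605 without the shared control). The MYMLR siRNAs correlated with each other at 0.431 (simulated 0). Calls shared between siMYMLR#1 and siMYC were 4240 rises and 2715 falls (independent lists 2001.3 and 1068.7), between siMYMLR#2 and siMYC 3813 and 2613 (1988 and 1173.2), and between siPCBP2 and siMYC 3953 and 2696 (2029.6 and 1188.4, with all 3 controls shared, from which part of the excess may come). Between siMYMLR#1 and siMYMLR#2 they were 3669 and 2394 (2085.5 and 1096.2). Those genes called in opposite directions numbered 1040, 1836, 1704 and 2010 in the same order.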

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

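Tests of normalization, MYC level, loss of target RNA, shared control arrays and the control siRNA were chosen after the results they concern were seen.

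The MYMLR siRNAs differed in MYC (-0.41, siMYMLR#1 minus siMYMLR#2), in PCBP2 (0.69) and in 15 gene lists by their own test. Their median differences were 0.32 for MYC-induced genes, 0.16 for ribosome biogenesis, -0.48 for cytosolic ribosomal proteins, 0.44 for nucleotide synthesis, 1.69 for S phase, 2.07 for mitosis, -0.50 for p53 targets and -0.32 for interferon-stimulated genes. They were 1.12 for NF-kB and cytokines, -0.43 for amino acid and ER stress, 0.52 for TGF-beta targets, 0.72 for replication-dependent histones, -0.45 for the respiratory chain, 0.58 for chaperones and 0.78 for poly(C)-binding and hnRNP genes. With an estimated correlation the last alone held (adjusted p = 0.0236). Without the pairing the calls for ribosome biogenesis (0.08, adjusted p = 0.425), for amino acid and ER stress (0.13, adjusted p = 0.888) and for MYC (-0.17, adjusted p = 0.484) were lost. Among 102 measures in the 8 control arrays, 2 had an array that stood apart from the others, where chance gives about 1 in 20: TMEM50A in sicontrol replicate 8 (0.20, the others 0.03 to 0.11) and the median level of the MYC/MAX/MXD network in sicontrol replicate 1 (-0.24, the others -0.13 to -0.02).

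The first pattern is the deep fall of 126 S-phase and mitosis genes after siMYMLR#2 (median -2.066), against -0.183 after siMYMLR#1. After siPCBP2 (slides 2 and 3) it was -1.02, so siMYMLR#2 was not alone. High levels in the controls of slide 4 are argued against, since siMYMLR#2 set against the controls of the other slides gave a median of -2.115 (quartiles -2.542 to -1.514), and so is the normalization, since the weakest of 6 others gave a difference of -1.808 where the one used gave -1.833. The lower MYC level alone is argued against as well, because siMYC, which lowered MYC about as far, moved these genes by a median of -0.116 (quartiles -0.352 to 0.052). Stronger loss of MYMLR with siMYMLR#2, effects of its sequence on other RNAs and a batch effect stay open and may all hold. MYMLR was not measured, slide 4 held no other knockdown, and MYC was lower after siMYMLR#1 (-0.406).

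The second pattern is the opposite move of ribosomal protein genes, lower after siMYC and higher after siPCBP2. A bent response of bright probes is argued against by 218 other genes of the same brightness, whose median difference was -0.102 (quartiles -0.315 to 0.774) against 1.036 for the ribosomal proteins, and a slide effect by the difference of at least 1.008 within slides 2 and 3. Normalization stays open: with the Cy5 channel alone the difference was 0.484 and the rise after siPCBP2 was not called (0.055, adjusted p = 0.206), so neither the size of 1.036 nor the rise can be told apart from the scaling. With an estimated correlation no call held (adjusted p = 0.135 after siMYC, 0.394 after siPCBP2 and 0.242 between them). A biological difference between losing MYC and losing PCBP2 could account for the rest, and its mechanism was not tested.

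The third pattern is the large set of genes that moved together after all 4 siRNAs. Shared control arrays are argued against as the whole source, since siRNAs with no control in common still correlated at 0.431 or more. The lower MYC level is a candidate explanation for part of it: 54.4% of the MYC-induced genes (31 of 57) fell after all 4, against 5.55% of all genes. An effect of the control siRNA itself, which would enter every comparison alike, cannot be told apart from a shared response, because 0 other control siRNAs or untreated samples were among these arrays.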

How the results depend on the processing

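Alternatives without the arrays of slide 1 or of slide 3 were chosen after the data were seen. MYC after each siRNA and PCBP2 after siPCBP2 kept direction and call in all 222 alternative values, as did MYC-induced and MYC promoter-bound genes in all 380 (medians -0.98 to -0.33). Counts of called genes stayed within 1.5 times in 296 of 304 values. The others carried the 2-fold minimum, by its construction: 1234 for siMYMLR#1, 2068 for siMYMLR#2, 1492 for siMYC, 1987 for siPCBP2, 1151 for both MYMLR siRNAs, 2007 between them, 879 for MYMLR against siMYC and 1708 for siPCBP2 against siMYC.

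Correlations of changes held their sign throughout, with 277 of 312 values within the spread of replicates. The others, in the order siMYMLR#1 with siMYC, siMYMLR#2 with siMYC, siMYMLR#2 with siPCBP2 and siMYMLR#1 with siMYMLR#2 unless named, follow, and the cause was not tested. With no replicate block they were 0.553, 0.502, 0.564 and 0.344, and siMYMLR#1 with siPCBP2 0.395. Feature Extraction log ratios gave 0.585, 0.440, 0.466 and 0.389, processed signals with loess 0.583, 0.440, 0.468 and 0.390, and the deposited values 0.585, 0.440, 0.466 and 0.388, with both MYMLR siRNAs against siPCBP2 at 0.553, 0.554 and 0.553. Median centring gave 0.591 and 0.454 with siMYC and 0.463 between the MYMLR siRNAs. Spearman gave 0.566, 0.430, 0.483 and 0.389, with 0.418 for siMYMLR#1 and 0.537 for both against siPCBP2. Without slide 3 they were 0.553, 0.452, 0.521 and 0.411, with 0.422 for siMYMLR#1 and siPCBP2. Leaving out each array in turn, the MYMLR siRNAs correlated at 0.411 to 0.437, lowest without siMYMLR#1 replicate 3. A 2-fold minimum cannot change a correlation over all genes and was not run there.

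Among other list results, 3 reversed, and the cause was not tested: ribosomal proteins over both MYMLR siRNAs, where the test turned with processed signals and loess (median 0.048) and the median with median centring (-0.197), and interferon-stimulated genes in MYMLR against siMYC without slide 3 (-0.336). Of 12949 other values of named genes, 30 lost and 5 gained their call. Of 10868 other list values, 239 lost and 174 gained it, 124 of the losses with the estimated correlation. Outside these results, the fit without the block ended the calls of 4 named gene results, and for gene lists it ended 16 and added 10 of 296. Aquantile scaling moved no ratio. Low signal limits the weak genes.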

Other observations

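Small RNA families and the 4-siRNA overlap were picked only after their values were seen. The counts over other splits of the arrays were planned.

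Small nucleolar RNAs, which guide modification of ribosomal RNA, fell after siMYC more often than after the other siRNAs. Of 132 C/D box RNAs, 96 fell and 7 rose after siMYC (median -0.53, between -0.97 and -0.53 over the normalizations), against 58 falls after siMYMLR#1, 53 after siMYMLR#2 and 38 after siPCBP2. In the difference of siPCBP2 and siMYC itself, 91 were higher after siPCBP2 and 1 lower (median 0.41, between 0.41 and 0.79), and for the MYMLR siRNAs against siMYC 69 were higher and 2 lower (median 0.28, between 0.22 and 0.65). Of 100 H/ACA box RNAs, 65 fell and 2 rose after siMYC (median -0.33, between -0.64 and -0.28). Small Cajal body RNAs, which guide modification of spliceosomal RNA, did otherwise: of 22, 15 rose and 0 fell after siPCBP2 (median 0.81, between 0.81 and 1.38 over the normalizations), 14 rose and 1 fell after siMYMLR#1 (0.545, between 0.495 and 1.13), 8 rose and 2 fell after siMYMLR#2 (0.08, between 0.08 and 0.36), and 3 rose and 5 fell after siMYC (-0.17, between -0.29 and -0.10). Most of these RNAs carry no poly(A) tail while the label was primed with oligo-dT, and whether the probes read the mature RNAs, precursors or host transcripts was not tested.

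Metallothionein genes, which bind zinc and copper, parted the MYMLR siRNAs: of 12, 10 rose after siMYMLR#1 (median 0.49, 0.19 to 0.51). After siMYMLR#2, 5 fell and 0 rose (-0.27, -0.50 to -0.24). Between them 9 differed, all higher with siMYMLR#1. After siMYC 8 rose (median 0.79) and after siPCBP2 9 rose (median 0.36). SNAR RNAs, whose probes share near-identical copies and are not independent, fell in 9 of 12 cases after siMYMLR#2 (median -2.36, -2.49 to -0.49). They fell in 7 after siMYMLR#1 (-0.91, -1.41 to -0.29) and 6 after siPCBP2 (-0.35, -0.45 to -0.23). There were 0 calls after siMYC (0.03, -0.10 to 0.03). Of 18 ANXA symbols, including ANXA2R and pseudogenes, 16 rose and 1 fell after siMYC (median 0.86) and 9 and 1 after siPCBP2 (0.30). Counts were 13 and 4 after siMYMLR#1 (0.32, 0.07 to 0.37) and 8 and 6 after siMYMLR#2 (0.03, -0.02 to 0.12). ANXA1 fell after every siRNA (-3.27, -2.27, -1.59 and -2.18).

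Counts over other splits of the same arrays bear on chance among these samples only, as the labels do not say that replicates were separate cultures. For siMYMLR#1 the real split called 10112 genes within its 6 arrays, for siMYMLR#2 12910, for siMYC 10560, for siPCBP2 11285, for siMYMLR#1 against siMYMLR#2 10073 and for siPCBP2 against siMYC 11400. In each of these 1 of 10 splits, the real one, reached that count and the highest other was 0, but 10 splits are too few for a share below 0.05. For both MYMLR siRNAs, 1 of 100 splits drawn from 462 reached the real 8045 (highest other 1211), a share below 0.05. Among the 32 drawn that part every pair it was likewise 1. For MYMLR against siMYC, 3 of 84 splits reached the real 2820, a share below 0.05, so the siRNAs did not part the pairs as at random. All 3 set 1 siRNA against the other 2, and the real one called the fewest: 3499 genes were called with the siMYMLR#1 pairs apart and 7024, the highest, with the siMYMLR#2 pairs apart. That is a structure of the samples by siRNA, so the count does not show that the MYMLR siRNAs together differ from siMYC.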
